A study of Mus musculus with 36 samples.

How the data were processed

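The series measured RNA of mouse liver on 1-colour Affymetrix arrays. Livers came from C57BL/6 WT and TB mice at 6 Zeitgeber times (ZT, every 4 h from 0 to 20), and each of the 12 groups of genotype and time had 3 arrays, 36 in all. The groups and replicate numbers were taken from the sample titles. Per the labels' protocols, livers were flash frozen, RNA was taken up with Trizol and cleaned on RNeasy columns, and biotin-labelled target was made with terminal transferase.

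The deposited values are probe set signals in units of linear intensity, 1 value per probe set and array, for 41345 probe sets. Per the submitters' processing notes the tools were Affymetrix Expression Console 1.1.1 and PLIER 2.0. The settings of these tools and the normalization between arrays are not given in the sources used here. Array medians lay between 36.3 and 43.3 intensity units, no pair of arrays held identical values, and 23.0% of all values were under 16. The number of arrays, 3 per group, limits the precision.

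Probe sets were named through the platform annotation, which listed 25335 of them. Of these, 23521 had 1 gene symbol and 1814 had several, and 16010 probe sets had no symbol. Of those with 1 symbol, 23328 (99.2%) matched the RefSeq gene table of assembly GRCm38.p6 by Entrez identifier, and the others kept the symbol of the annotation. Where several probe sets shared a gene (1082 genes), the 1 with the highest mean over all arrays was used, which left 22180 genes. Values were turned into log2(value + 16), so a difference understates the change of genes near or under 16 intensity units. No further normalization and no filter were applied in the chosen setting. The transgenic genes of the model are not analysed here.

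Tests were made with limma 3.58.1 in R 4.3.3 (lmFit and eBayes). The 36 arrays were fitted with 12 group means and a shared spread. The genotype difference was the mean of the 6 TB groups minus the mean of the 6 WT groups, each ZT was tested by its own contrast, and the dependence on time by an F test of the differences between the 6 contrasts. Rhythms were tested with a mean, a cosine and a sine term of 24 h for each genotype. F tests of the cosine and sine terms gave rhythmic genes in WT and in TB, and an F test of equal terms gave differential rhythm. Amplitude is the height of the fitted cosine above its mean in log2, and peak time is ZT in h. Benjamini-Hochberg adjusted p-values were taken over all 22180 genes, with 0.05 as the threshold, and all tests were two-sided or F tests.

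Gene lists for pathways, cell types and tissues, 45 in all with 925 symbols, of which 830 were measured, were written before the data were examined, as were the designs, the rule for named genes and the other settings to be tried. The lists on inflammation, insulin, glucose and lipid metabolism and the genes always named were chosen with the subject of the series and prior knowledge of the study in mind. Lists with at least 5 measured members, 42 in all, were tested with camera at a preset correlation of 0.01 between genes. Each was also tested with an estimated correlation, with fry, which asks whether the genes of a list move on balance 1 way without comparing them with other genes, and by permutation of genotype within each ZT of the mean centred log2 value per array (100000 draws). The permutation was added after the data were seen, as was a test of the rhythm of these list scores. Overrepresentation of lists among rhythmic genes was tested with Fisher's exact test, one-sided, against all 22180 genes.

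Named genes were chosen by the rule as follows. For the genotype difference these were the 12 largest differences in each direction among genes past the threshold with 1 sign at all 6 ZT, and for each ZT the 3 largest in each direction. For the interaction and for rhythms in each genotype they were the 10 with the smallest p, and for differential rhythm 10 with lower and 10 with higher amplitude in TB. All core clock genes, up to 4 genes per list by smallest p, Xist, Ddx3y, Eif2s3y, Kdm5d and Uty, and Socs3, Stat3, Saa1, Saa2, Srebf1, Insr, Irs1, Irs2, G6pc, Pck1 and Fasn were named wherever measured, and some further genes of this rule are not reported here. Predicted and unnamed gene models were left out of the ranked parts. Genes named outside this rule are marked as chosen after their values were seen.

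The settings chosen in advance were a pseudocount of 1, quantile normalization, median centring, removal of the third of genes lowest in mean, the mean of probe sets per gene, all probe sets, the replicate number as a block, array weights, a variance trend with robust fitting, Xist as a covariate, additive time, only the arrays of a ZT or genotype, a 6-level time factor, a Kendall rank test against 24 h cosine templates, adjustment over rhythmic genes, an estimated correlation, fry, and each array left out in turn. After the data were seen, fits without ZT 0 and with 2 sets of arrays were added. The sets are the arrays on either side of the gap in the first principal component of the deviations from group means of 10493 probe sets that have no symbol and enter no gene test. They were used as a block, as a block without 1 array that held muscle transcripts, and each alone, with additive time for the smaller set, whose lists were also tested without that array. Within each set, list means were tested by exact permutation of genotype inside each ZT (46656 arrangements in the larger set and 64 in the smaller). Lists of skeletal muscle genes and of cytosolic and mitochondrial ribosomal protein genes were also added after the data were seen.

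The tests were checked on simulated data made from the real means and spreads of the 22180 genes. Noise was drawn independently for each gene and array, with no relation between genes and no array sets. The shares below therefore describe such data and may not hold for the real arrays. With 200 genes changed between genotypes, the mean contrast found 56.7%, 94.0% and all 100% of changes of 0.25, 0.5 and 1 log2, and 2.34% of its calls were false. For differential rhythm the shares were 13.4%, 79.1% and 97.0%, with 5.26% false calls. For rhythms in WT (400 genes) they were 42.5%, 97.8% and 100%, and in TB 38.8%, 95.5% and 100%.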

Results

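The series asked how a lung adenocarcinoma relates to the daily program of gene expression in the distant liver. Expression was measured in livers of WT mice and of TB mice, the tumour-bearing animals of the study, all on a C57BL/6 background and kept under 12 h of light and 12 h of dark. Livers were taken every 4 h from ZT 0 to ZT 20, counted in hours from lights on. Each of the 12 groups held 3 arrays, so that 18 arrays stood for each genotype. Values are probe set intensities made by the authors, taken here as log2(value + 16) for 22180 genes. Correlations over genes between arrays of a group ran from r = 0.929 to 0.989, and the median SD within groups was 0.18 log2. The replicates are separate samples by their labels, which do not say for each that it is another mouse, so p-values measure the spread between these samples, which may in part be technical.

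Skeletal muscle genes stood out in 1 array. In WT ZT 12 replicate 3, Ttn, the giant spring protein of the sarcomere, was at 16.8 log2 against a median of 5.45 in the 35 other arrays, and Ckm, the creatine kinase of muscle, was at 16.7 against 6.18. All 24 measured muscle genes were higher there than in every other array, by a median of 6.52 log2 over the median of the others. Over all arrays the muscle list differed by −0.38 between TB and WT, by −0.0094 in the 24 arrays and by −1.12 in the 12 arrays of the sets described next. The muscle list was written after this was seen.

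The arrays also fell into 2 sets. The component that separates them came from deviations from group means. By construction it could not follow genotype or time, and no group could lie wholly on 1 side. In each of the 12 groups 1 array belonged to a smaller set of 12 and the others to a larger set of 24, with positions of 16.8 to 25.1 and of −14.4 to −6.73 along the component that separates them, which took 33.6% of the variance within groups of probe sets without a symbol. Between the sets 6784 genes differed in limma (3778 higher and 3006 lower in the smaller set, median size 0.23 log2). The sets were found from the data and are not named in the labels. Yet at each ZT the array of the smaller set had the same replicate number in WT and TB (3, 1, 2, 3, 1 and 2 from ZT 0 to ZT 20). What the sets stand for was not tested. Values within each set are given below for the lists that camera called and for some of the genes and other lists.

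Averaged over the 6 times of day, TB livers had higher levels of several acute phase transcripts than WT livers. Fgl1, a secreted hepatocyte protein of the fibrinogen family, rose by 1.31 ± 0.285 log2 (SE, n = 18 per genotype, 2.48-fold; limma adjusted p = 0.0459), from a mean of 10.3 in WT to 11.6 in TB. The metal-binding Mt2 rose by 2.06 ± 0.423 (adjusted p = 0.0377) and Lcn2, which sequesters bacterial siderophores, by 1.84 ± 0.396 (adjusted p = 0.0442), each higher at 5 of 6 times. Il6st, the signalling subunit shared by receptors of the IL-6 family, rose by 0.36 ± 0.065 (adjusted p = 0.0168) and was higher at 6 of 6 times. Clca3a1 and Mustn1 had the smallest adjusted p-values (both 0.00104), with rises of 1.31 ± 0.186 and 1.13 ± 0.157, and Adam23 rose by 0.88 ± 0.131 (adjusted p = 0.00131). Mt2, Lcn2 and Il6st are named as members of the lists.

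In all, 39 genes passed, 26 higher and 13 lower in TB, each named difference below with an adjusted p between 0.00131 and 0.0459. Among the genes with 1 sign at all times, Selp, the P-selectin of activated endothelium and platelets, rose by 0.61 ± 0.128, the junction molecule Jam2 by 0.54 ± 0.098, the transglutaminase Tgm1 by 0.54 ± 0.113, the heparanase Hpse by 0.50 ± 0.083, Tmem176b by 0.50 ± 0.103, the matrix protein Tgfbi by 0.50 ± 0.098, Ankrd55 by 0.45 ± 0.068 and Fam171b by 0.45 ± 0.082. Only 9 lower genes met the rule for naming. The interferon-induced Ifit1 decreased by 0.46 ± 0.092 (adjusted p = 0.0291), and Med21, a subunit of the Mediator complex, decreased by 0.41 ± 0.072 (adjusted p = 0.0125). Ltbp4, which holds latent TGF-beta in the matrix, changed by −0.41 ± 0.082, and Tert, the catalytic subunit of telomerase, by −0.29 ± 0.057. The mitochondrial genes Atp5k (−0.27 ± 0.052), Mrpl42 (−0.24 ± 0.050) and Mmaa (−0.24 ± 0.051) were lower, as were Pde2a (−0.24 ± 0.052) and the kinase gene Map2k3 (−0.21 ± 0.045).

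At an unadjusted p under 0.05 there were 2449 genes, where 1109 are expected on average if no gene differs. Random splits of genotype within each ZT also gave 2472, 2721, 3519 and 4546 such genes, so this excess does not exclude chance. Taking the array set as a block, limma called 151 genes (71 higher, 80 lower), which held all 39 and also the list members Osmr (adjusted p = 0.0288), Itih4 (0.0309), Stat3 (0.0385) and Cyp8b1 (0.0473). The larger set alone called 1151 (331 higher, 820 lower), with 37 of the 39 among them, and the smaller set alone called 0 (1971 at an unadjusted p under 0.05; no other tool was run there). All 39 had the same sign in each set, which is no independent evidence since both sets entered the test. Over all genes the TB minus WT differences of the sets showed no positive relation (Pearson r = 0.0088 and Spearman rho = −0.12 across genes, which are not independent replicates). Of the 1151 genes called in the larger set 491 (42.7%) had the same sign in the smaller, against 43.5% of all genes. Fgl1 differed by 1.16 in the larger set and by 1.61 in the smaller, Clca3a1 by 1.40 and 1.13, Mustn1 by 1.22 and 0.96, and Adam23 by 0.91 and 0.80, whereas Ifit1 differed by −0.59 and −0.19 and Med21 by −0.52 and −0.19. Leaving out single arrays moved the count from 11 (without TB ZT 20 replicate 2) to 109 (without TB ZT 8 replicate 2). Clca3a1, Mustn1, Adam23, Jam2, Hpse, Ankrd55, Fam171b, Med21 and Il6st passed with every array left out, whereas Fgl1 lost its call in 26 of 36 cases, Lcn2 in 27 and Mt2 in 20.

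The acute phase list, secreted proteins and metal-binding genes that hepatocytes raise in inflammation, stood higher in TB as a group. Of its 26 measured genes 25 had a positive difference, with a mean of 0.58 and a median of 0.37 log2. Over all genes 3 of them rose (Mt2, Lcn2 and Fgl1) and 0 fell, and adjusted over the list alone 19 rose and 0 fell. Itih4 differed by 0.42 ± 0.098 (adjusted p = 0.0711 over all genes, n = 18 per genotype) and the serum amyloid gene Saa2 by 1.26 ± 0.446 (adjusted p = 0.255). Of the 22 genes on IL-6 and STAT3 signalling 19 had a positive difference, with a mean of 0.21 and a median of 0.12. Il6st rose over all genes, and adjusted over the list alone 8 genes rose, among them the oncostatin M receptor Osmr at 0.54 ± 0.120, the transcription factor Stat3 at 0.44 ± 0.112 and the interleukin 1 receptor Il1r1 at 0.63 ± 0.174. Socs3, the feedback inhibitor of this pathway, differed by 0.64 ± 0.204 (adjusted p = 0.202 over all genes).

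Camera called the acute phase list with adjusted p = 5.3e-19, and the call was lost at adjusted p = 0.207 with an estimated correlation. The IL-6 and STAT3 list was called with adjusted p = 8.6e-06, lost at adjusted p = 0.224 with an estimated correlation. By fry, which tests whether genes of a list move on balance 1 way and does not compare them with other genes, each had an adjusted p of 0.0435, and permutation of genotype within each ZT gave adjusted p = 0.0386 and 0.0357. Camera with the set as a block gave adjusted p = 1.1e-18 (0.304 with an estimated correlation) for the acute phase list and 1.1e-05 (0.310 with an estimated correlation) for the IL-6 and STAT3 list. The acute phase mean was 0.53 in the larger set and 0.68 in the smaller (exact permutation p = 0.0341 and 0.0313), and the IL-6 and STAT3 mean 0.17 and 0.28 (exact permutation p = 0.0277 and 0.0313), where 0.0313 is the smallest p the smaller set allows. None of these 4 p-values passed adjustment over the lists in its set. Both lists were chosen with the study in mind, so their direction is not independent evidence.

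The spread of the acute phase genes within groups was uneven. At ZT 0 the list differed by −0.12 between TB and WT and at ZT 12 by 0.48, against 0.91, 1.03 and 1.00 at ZT 4, 8 and 16 and 0.19 at ZT 20. The SD of the WT scores was 0.77 at ZT 0 and 1.02 at ZT 12. In each of these groups 1 WT array scored above all others of its group, WT ZT 0 replicate 2 at 1.17 and WT ZT 12 replicate 1 at 1.16. Without these arrays the differences were 0.27 at ZT 0 and 1.06 at ZT 12, whereas they were −0.51 at ZT 0 without TB ZT 0 replicate 1 and 0.083 at ZT 12 without WT ZT 12 replicate 3 (0.31 without replicate 2 of that group). The difference at ZT 20 was 0.040 without TB ZT 20 replicate 2, 0.082 without WT ZT 20 replicate 2, 0.35 without TB ZT 20 replicate 3 and 0.36 without WT ZT 20 replicate 1.

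**Figure D1:**
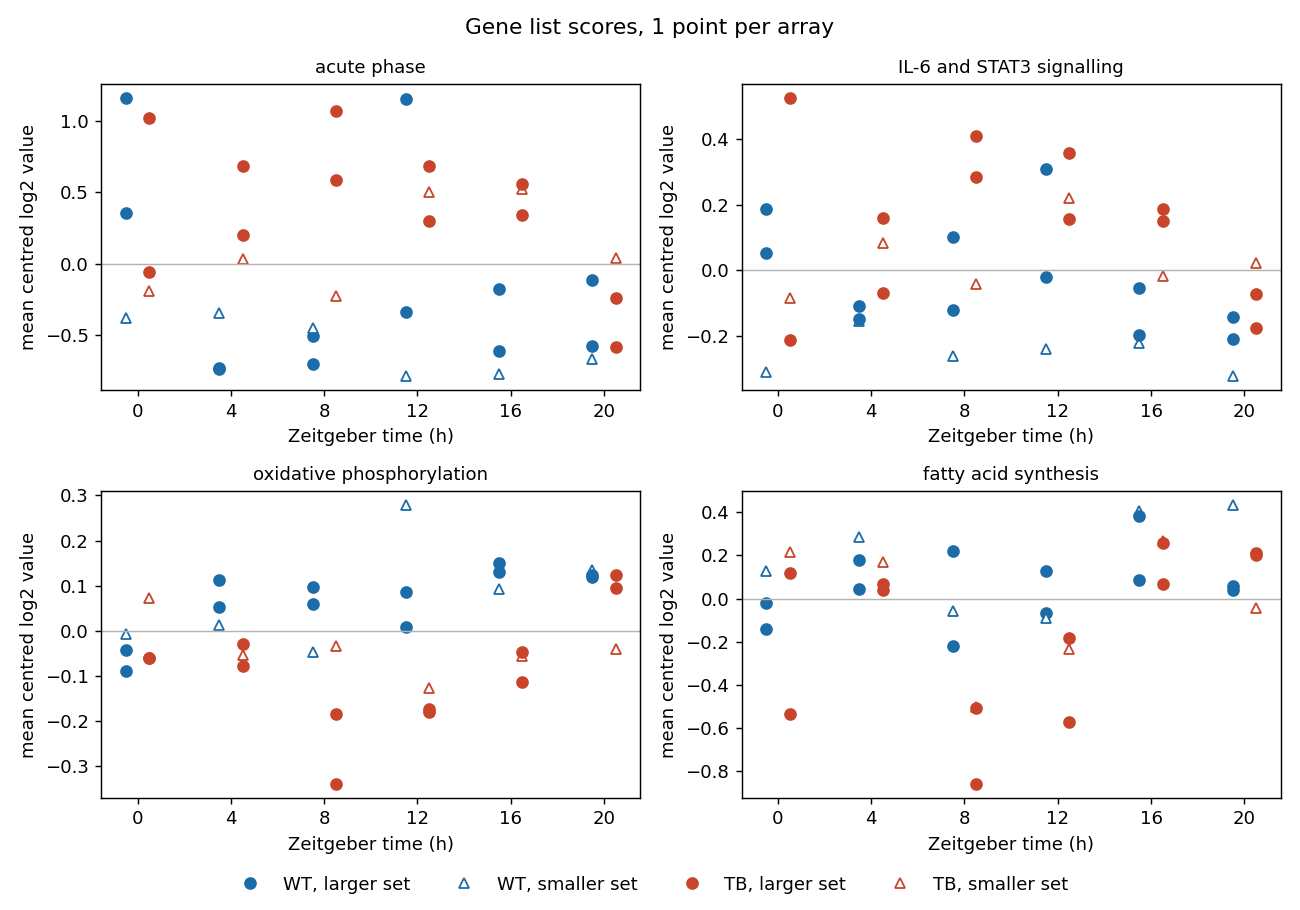
Mean centred log2 level per array (vertical axis) of the acute phase, IL-6 and STAT3, oxidative phosphorylation and fatty acid synthesis lists against ZT in h (horizontal axis), with WT in blue and TB in red, circles for the larger array set and triangles for the smaller. The mean TB minus WT differences were 0.58, 0.21, −0.14 and −0.20, and WT arrays at ZT 0 and ZT 12 reached 1.17 and 1.16 on the acute phase panel.

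Averaged over the times of day, genes of mitochondrial respiration were lower in TB. All 31 measured genes of oxidative phosphorylation had a negative difference, with a mean and median of −0.14 log2. Uqcrfs1, the Rieske iron-sulfur protein of complex III, decreased by 0.19 ± 0.041 (adjusted p = 0.0489, n = 18 per genotype) and was the 1 gene called over all genes, while 14 fell adjusted over the list alone. Among these 14 were the complex I subunits Ndufs1 at −0.24 ± 0.055, Ndufa2 at −0.19 ± 0.051 and Ndufa9 at −0.16 ± 0.044. The decrease did not hold at every time. At ZT 0 the list differed by 0.030 between TB and WT. At ZT 20 the WT arrays scored 0.12, 0.14 and 0.12 and the TB arrays 0.095, −0.040 and 0.12. Only TB ZT 20 replicate 2 lay far below the WT scores there. This list was called by each of 4 tests, with adjusted p = 1.5e-18 by camera, 0.00587 with an estimated correlation, 0.000198 by fry and 0.00126 by permutation, and it was the only 1 of the 15 lists called by camera that kept its call with an estimated correlation. Under the block the adjusted p was 2.2e-25, and 0.0527 with an estimated correlation, which misses the threshold. The mean was −0.15 in the larger set and −0.12 in the smaller (exact permutation p = 0.000772, adjusted 0.0324, and 0.188). The muscle-bearing array had the highest score of all 36 for this list, 0.28, and without it the mean in the smaller set was −0.059 ± 0.048 (SE over 5 times, exact permutation p = 0.375).

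Fatty acid synthesis genes were also lower in TB as a group. Of 24 measured genes 22 had a negative difference, with a mean of −0.20 and a median of −0.14. Over all genes 0 were called in limma, and adjusted over the list alone 10 fell. Fasn, the fatty acid synthase, differed by −0.39 ± 0.089 (adjusted p = 0.0624 over all genes), Acly, which makes cytosolic acetyl-CoA, by −0.38 ± 0.092, the lipogenic transcription factor gene Srebf1 by −0.25 ± 0.085 and the acetyl-CoA carboxylase gene Acacb by −0.32 ± 0.109. Camera gave adjusted p = 8.2e-10, lost at adjusted p = 0.207 with an estimated correlation, fry 0.0435 and permutation 0.0737. Camera with the block gave adjusted p = 4.9e-09 (0.304 with an estimated correlation). The mean was −0.20 in each set (exact permutation p = 0.0615 in the larger and 0.0625 in the smaller).

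Glycolysis genes had a mean of −0.071 and a median of −0.053, with 14 of 18 negative. Over all genes 0 passed, and adjusted over the list alone 4 fell, Pygl (−0.22 ± 0.060), Pgk1 (−0.12 ± 0.037), Gckr (−0.14 ± 0.043) and the pyruvate kinase Pklr (−0.41 ± 0.127), and 1 rose, the lactate dehydrogenase gene Ldha (0.18), which is named here after its value was seen. Camera gave adjusted p = 0.00877, lost at adjusted p = 0.207 with an estimated correlation, fry 0.0435 and permutation 0.0842. Under the block it was 0.0151 (0.310 with an estimated correlation), and the mean was −0.088 in the larger set and −0.036 in the smaller, or −0.0011 there without the muscle-bearing array. For fatty acid oxidation and PPAR-alpha targets 20 of 30 genes were negative, with a mean of −0.066 and a median of −0.095. The camera call (adjusted p = 0.00869) was lost at adjusted p = 0.688 with an estimated correlation, 0 genes passed over all genes or adjusted over the list alone, and Acadl, the most extreme by p, differed by −0.11 ± 0.048. With the block the adjusted p was 0.00849 (0.697 with an estimated correlation), and the means were −0.049 and −0.10 in the larger and smaller set. The mean was −0.031 without WT ZT 12 replicate 2, which ended the call (adjusted p = 0.0921), and −0.11 without WT ZT 12 replicate 1.

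Heat shock chaperones were lower, with 13 of 15 negative, a mean of −0.14 and a median of −0.15. Over all genes 0 passed and adjusted over the list alone 4 fell, the mitochondrial chaperonin Hspd1 (−0.19 ± 0.047), Hspa4l (−0.28 ± 0.086), Fkbp4 (−0.24 ± 0.074) and Stip1 (−0.19 ± 0.071). Camera gave adjusted p = 4.3e-06, lost at adjusted p = 0.224 with an estimated correlation, fry 0.0815 and permutation 0.0842, and camera with the block 2.0e-05 (0.356 with an estimated correlation). The mean was −0.22 in the larger set and −0.00072 in the smaller, or 0.0036 there without the muscle-bearing array.

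For 5 further lists that camera called lower, the mean had the opposite sign in the smaller set. Interferon response genes (17 of 21 negative, mean −0.12, median −0.13) had 1 member called over all genes, Ifit1, and 2 adjusted over the list alone, Ifit1 and Bst2 (−0.38 ± 0.118). Their adjusted p was 8.6e-06, lost at adjusted p = 0.375 with an estimated correlation. Their mean was −0.23 in the larger set (exact permutation p = 0.0021, adjusted 0.0441) and 0.094 in the smaller (exact permutation p = 0.375). A pass of this test in the larger set thus did not go with the same sign in the smaller. Male-biased liver genes (20 of 23 negative, mean −0.30, median −0.33; adjusted p = 0.000148, lost at adjusted p = 0.676 with an estimated correlation) included the urinary protein gene Mup21 at −0.88 ± 0.317 and Cyp4a12a at −0.85 ± 0.310. The 1 member called, over all genes and adjusted over the list alone, was Cspg5, which rose by 0.24 ± 0.048. Their mean was −0.50 in the larger set and 0.11 in the smaller, the SD of the 3 TB scores at ZT 0 was 1.59, and without TB ZT 0 replicate 1 the mean over all arrays was −0.15 (adjusted p = 0.00978). Phase II conjugation genes (mean −0.088; adjusted p = 0.00101, lost at adjusted p = 0.375 with an estimated correlation), with Ugt2b5 at −0.24 ± 0.086, had means of −0.16 and 0.055. Unfolded protein response genes (mean −0.057; adjusted p = 0.0151, lost at adjusted p = 0.688 with an estimated correlation), with the endoplasmic reticulum chaperone Hyou1 at −0.26 ± 0.111 and the asparagine synthetase Asns at 0.73 ± 0.258, had means of −0.16 and 0.14. Ribosome biogenesis genes (mean −0.050; adjusted p = 0.0364, lost at adjusted p = 0.695 with an estimated correlation), with Myc at −0.31 ± 0.141, had means of −0.11 and 0.078. In the last 3 of these lists 0 genes passed, over all genes or adjusted over the list alone. With the block the adjusted p-values of the 5 lists were 2.4e-05, 0.000618, 0.00334, 0.0186 and 0.0466, and 0.553 to 0.697 with an estimated correlation. Without the muscle-bearing array their means in the smaller set were 0.055, 0.21, 0.078, 0.16 and 0.051. With single arrays left out the ribosome biogenesis mean ran from −0.066 to −0.033 and its call was lost in 16 of 36 cases, with adjusted p up to 0.208 without TB ZT 0 replicate 2. The unfolded protein call was lost without WT ZT 12 replicate 1 (mean −0.031, adjusted p = 0.139), TB ZT 0 replicate 1 (−0.033, 0.0730) and WT ZT 16 replicate 3 (−0.045, 0.0509).

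**Figure D2:**
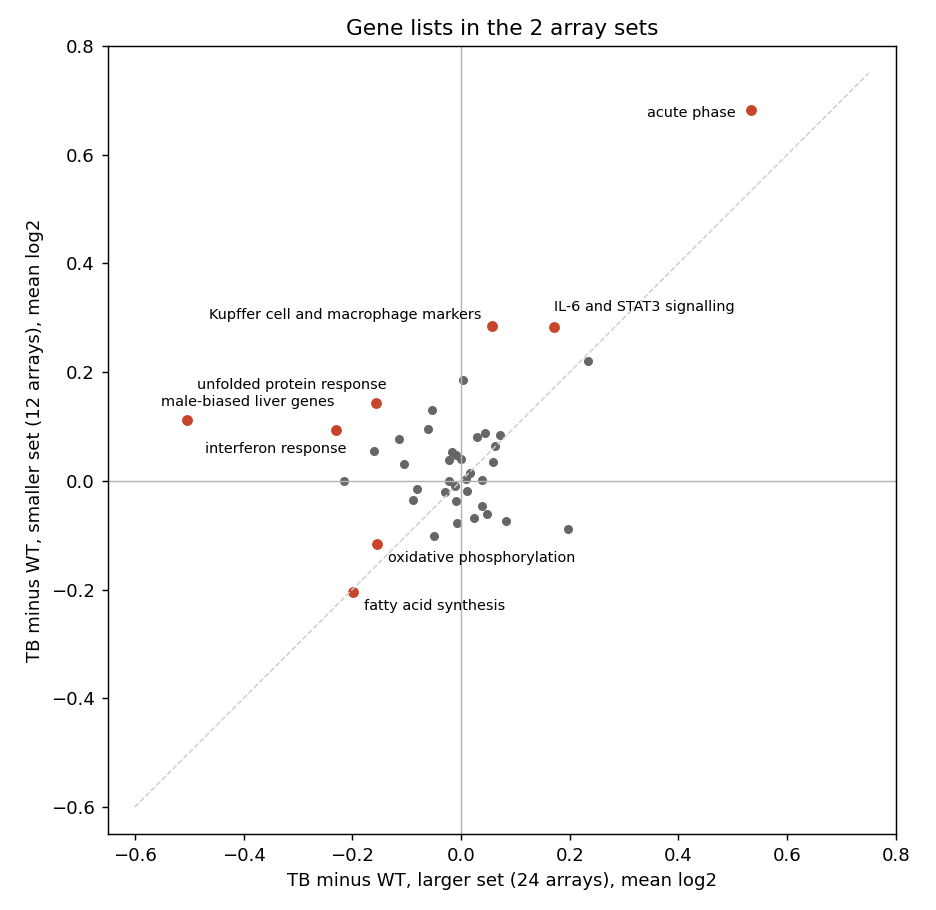
Mean TB minus WT difference in log2 of each of the 42 gene lists in the larger array set (horizontal axis) and in the smaller (vertical axis), 1 point per list, the labelled lists in red, with the dashed line marking equal values. The acute phase list lies at 0.53 and 0.68, whereas the male-biased list lies at −0.50 and 0.11, and 24 of 42 lists have the same sign in both sets.

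Camera also called 3 lists higher besides the acute phase and IL-6 lists. Kupffer cell and macrophage markers had a positive difference in 17 of 19 genes (mean 0.13, median 0.11), with the scavenger receptor Marco at 0.69 ± 0.227. Their adjusted p was 0.0125, lost at adjusted p = 0.746 with an estimated correlation, and 0 genes passed over all genes or adjusted over the list alone. Neutrophil and monocyte markers were positive in 16 of 19 (mean 0.059, median 0.052; adjusted p = 0.0250, lost at adjusted p = 0.375 with an estimated correlation). The neutrophil elastase gene Elane rose by 0.26 ± 0.056 (adjusted p = 0.0442) and was the 1 gene called over all genes and adjusted over the list alone. Complement and coagulation genes (16 of 26 positive, mean and median 0.064; adjusted p = 0.0321, lost at adjusted p = 0.746 with an estimated correlation) had 0 called over all genes and 3 risen adjusted over the list alone, Cfi (0.24 ± 0.060), Hc (0.28 ± 0.079) and C4b (0.40 ± 0.126). The means in the larger and smaller set were 0.058 and 0.28 for Kupffer cells, 0.044 and 0.088 for neutrophils and 0.0038 and 0.19 for complement. With the block the adjusted p-values were 0.0170, 0.0279 and 0.0177 (0.763, 0.553 and 0.697 with an estimated correlation). With single arrays left out the complement call was lost in 12 of 36 cases, with a mean of 0.038 and adjusted p = 0.352 without WT ZT 12 replicate 3. The Kupffer cell call was lost in 6 cases (up to adjusted p = 0.114, without the same array) and the neutrophil call in 5 (up to 0.0653, without WT ZT 8 replicate 3).

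Markers of other cells and tissues were not called. The camera adjusted p was 0.990 for lymphocytes (mean 0.011), 0.954 for endothelial cells, 0.617 for cholangiocytes, 0.340 for red cells and platelets, 0.954 for extracellular matrix genes (Dcn at 0.25 ± 0.079 and Timp3 at −0.38 ± 0.090 passed adjusted over the list alone), 0.6999 for cell cycle genes and 0.617 for hepatocyte identity genes. Lung epithelium markers had adjusted p = 0.377, with the surfactant protein gene Sftpa1 (0.24 ± 0.071) passing adjusted over the list alone, and markers of pancreas, fat and gut 0.954, with the trypsinogen gene Prss2 (0.22 ± 0.067) passing likewise. Among stellate cell and fibroblast markers (adjusted p = 0.617; median −0.0094 but mean 0.031, with the test upward) 4 rose adjusted over the list alone, such as Hgf, the hepatocyte growth factor gene (0.33 ± 0.083), and 1 fell, Reln (−0.24 ± 0.078). The X-linked Xist, which silences the X chromosome of females, differed by 0.11 ± 0.049 (adjusted p = 0.361), and the Y-linked Kdm5d by −0.12 ± 0.051, Eif2s3y by 0.025 ± 0.070 and Uty by 0.0076 ± 0.055, none of them called. Mean levels of Xist were 5.34 log2 in WT and 5.46 in TB (SD 0.15 and 0.14). Those of Kdm5d were 6.90 and 6.79, of Eif2s3y 7.77 and 7.80 and of Uty 7.30 and 7.31. Eif2s3y and Uty had the opposite sign after median centring, at −0.0045 and −0.022.

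Lists on glucose, sterols and other liver functions were not called either. Insulin and growth factor signalling had adjusted p = 0.487, with a mean of 0.0079 against a median of −0.021 and a downward test. In the larger set camera called it lower (mean −0.053, adjusted p = 0.0343, lost at adjusted p = 0.568 with an estimated correlation) and in the smaller set higher (mean 0.13, adjusted p = 0.0232, lost at adjusted p = 0.794 with an estimated correlation). Irs1, an adaptor of the insulin receptor, differed by −0.17 ± 0.084, Irs2 by 0.088 ± 0.126 and Insr by 0.084 ± 0.045. Gluconeogenesis had adjusted p = 0.980, with a positive mean of 0.063 against a downward test, and G6pc differed by −0.17 ± 0.122 and Pck1 by 0.19 ± 0.142. Without TB ZT 0 replicate 1, Irs2 differed by 0.013 and Pck1 by 0.077, whereas Irs2 reached 0.15 without TB ZT 0 replicate 2 and Pck1 0.28 without TB ZT 0 replicate 3. Cholesterol synthesis had adjusted p = 0.366 (mean 0.051). In the glucocorticoid response list (adjusted p = 0.659, mean 0.23) Mt2 and Lcn2, which also belong to the acute phase list, rose, and adjusted over the list alone Hsd11b1, which regenerates active glucocorticoid, fell (−0.19 ± 0.049). Bile acid synthesis (0.120) had Cyp8b1, the 12-alpha-hydroxylase gene, at −0.55 ± 0.133, the 1 gene passing adjusted over the list alone. In the iron and heme list (0.127) Bmp6, Hjv and Hamp2, genes of hepcidin and its control, had differences of −0.28 ± 0.072, −0.22 ± 0.058 and −0.88 ± 0.301 and passed adjusted over the list alone. The adjusted p was 0.161 for NF-kB targets, 0.0724 for urea cycle and amino acid catabolism, 0.617 for lipoproteins, 0.472 for immediate early genes and 0.226 for female-biased genes (mean 0.10). It was 0.678 for cytochrome P450 genes (mean −0.0082 but median 0.012; Cyp3a13 at 0.43 ± 0.121 passed adjusted over the list alone) and 0.617 for NRF2 targets (mean 0.0077 but median −0.017, downward test). Autophagy (0.617) and NAD and one-carbon metabolism (0.230) each had 1 gene higher adjusted over the list alone, Map1lc3b (0.22 ± 0.057) and Mthfd1l (0.22 ± 0.065). Core clock genes (0.617) and clock-controlled output genes (0.958) were not called for their mean level. With single arrays left out, camera called NF-kB targets without WT ZT 0 replicate 2 (adjusted p = 0.0324), bile acid synthesis and NAD metabolism without WT ZT 12 replicate 3 (0.0319 and 0.0315), and urea cycle genes in 11 of 36 cases (lowest 0.0108, without TB ZT 0 replicate 1). With the array set as a block camera called urea cycle genes (adjusted p = 0.0466, lost at adjusted p = 0.697 with an estimated correlation). Cholesterol synthesis was called after quantile normalization (adjusted p = 0.0281) and with the Xist covariate (0.0133), which also called the female-biased list (0.0043). Among 4 measured ketone body genes, too few for a list test, Bdh1 differed by −0.19 ± 0.097.

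At single times of day, limma called Nav2 at ZT 8, where it decreased by 0.91 ± 0.155 (adjusted p = 0.0455, n = 3 per group). At ZT 0, 4, 12, 16 and 20 limma called 0 genes, with lowest adjusted p-values of 0.448, 0.176, 0.199, 0.317 and 1. Unadjusted p-values under 0.05 numbered 1051, 722, 1175, 1641, 1194 and 401 from ZT 0 to ZT 20, and no other tool was run. On average 1109 are expected if no gene differs, but such counts vary widely where genes move together. The larger set alone called 28 genes at ZT 8 and with the set as a block 2 were called. Leaving out WT ZT 12 replicate 1 raised the count at ZT 12 to 20, leaving out TB ZT 0 replicate 2 raised that at ZT 0 to 5 and WT ZT 0 replicate 3 to 1, leaving out WT ZT 4 replicate 3 raised that at ZT 4 to 1, and leaving out TB ZT 8 replicate 2 raised that at ZT 8 to 7. Nav2 lost its call in 21 of 36 cases of a left-out array. The F test for a genotype difference that depends on time called 0 genes in limma (550 at an unadjusted p under 0.05; lowest adjusted p = 0.0928), and 3 without TB ZT 8 replicate 2, 2 without WT ZT 8 replicate 1 or TB ZT 0 replicate 2, and 1 without WT ZT 8 replicate 2.

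By time of day, camera called 10, 9, 10, 15, 20 and 4 lists at ZT 0 to ZT 20, and with an estimated correlation 1 at ZT 8, 1 at ZT 12 and 0 at the other times. Fatty acid synthesis genes had their lowest difference at ZT 8, with a mean of −0.60 (adjusted p = 4.5e-19, and 0.0268 with an estimated correlation, n = 3 per group by limma's camera). Oxidative phosphorylation genes had theirs at ZT 12, with a mean of −0.28 (adjusted p = 8.4e-16, and 0.0131 with an estimated correlation by camera). With single arrays of those times left out, the calls with an estimated correlation held in 2 of 6 cases for fatty acid synthesis (up to adjusted p = 0.164, without WT ZT 8 replicate 3) and in 4 of 6 for oxidative phosphorylation (0.0917, with a mean of −0.21, without the muscle-bearing array). Cholesterol synthesis genes differed by 0.20 and 0.17 at ZT 0 and 4, by −0.18 and −0.33 at ZT 8 and 12 and by 0.34 at ZT 16, but by −0.038 at ZT 8 without WT ZT 8 replicate 3, and from −0.58 to −0.15 at ZT 12 and from 0.20 to 0.45 at ZT 16 with single arrays left out. Female-biased genes differed by 0.80 and male-biased genes by −0.77 at ZT 0, but by 0.41 and 0.14 without TB ZT 0 replicate 1.

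The core clock ran in livers of both genotypes. Of 14 measured core clock genes 13 were rhythmic in WT and 11 in TB, all 11 in both. Arntl, which encodes the activator BMAL1, had an amplitude of 1.83 ± 0.157 log2 in WT and 1.93 in TB (SE, n = 18 per genotype) and peaked at ZT 22.4 and 22.1. Its target Nr1d1, the REV-ERB-alpha repressor gene, had amplitudes of 2.50 and 2.28 (SE 0.173) and peaked at ZT 7.76 and 6.92. Npas2 peaked at ZT 23.9 and 23.6 with amplitudes of 2.07 and 1.90, and Clock at 22.5 and 22.6 with 0.57 and 0.69. The period genes followed, with Per1 at ZT 13.2 and 12.3 (amplitudes 1.43 and 1.23) and Per3 at 12.0 and 11.8 (1.43 and 1.19), and the repressor gene Cry1 at 19.5 and 19.3 (1.05 and 1.06). Cry2 had amplitudes of 0.37 and 0.29, Nr1d2 of 1.64 and 1.47, Ciart of 1.48 and 1.32 and Bhlhe40 of 0.42 and 0.44.

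Rora was rhythmic in neither genotype (adjusted p = 0.673 and 0.462). Csnk1e passed in WT (adjusted p = 0.0255) and not in TB (0.871), as did Bhlhe41 (0.00391 and 0.0750), but the tests of the difference itself gave adjusted p = 0.985 and 0.991, and for every core clock gene at least 0.985. The Cry2 rhythm in TB lost its call in 4 of 36 cases of a left-out array.

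**Figure D3:**
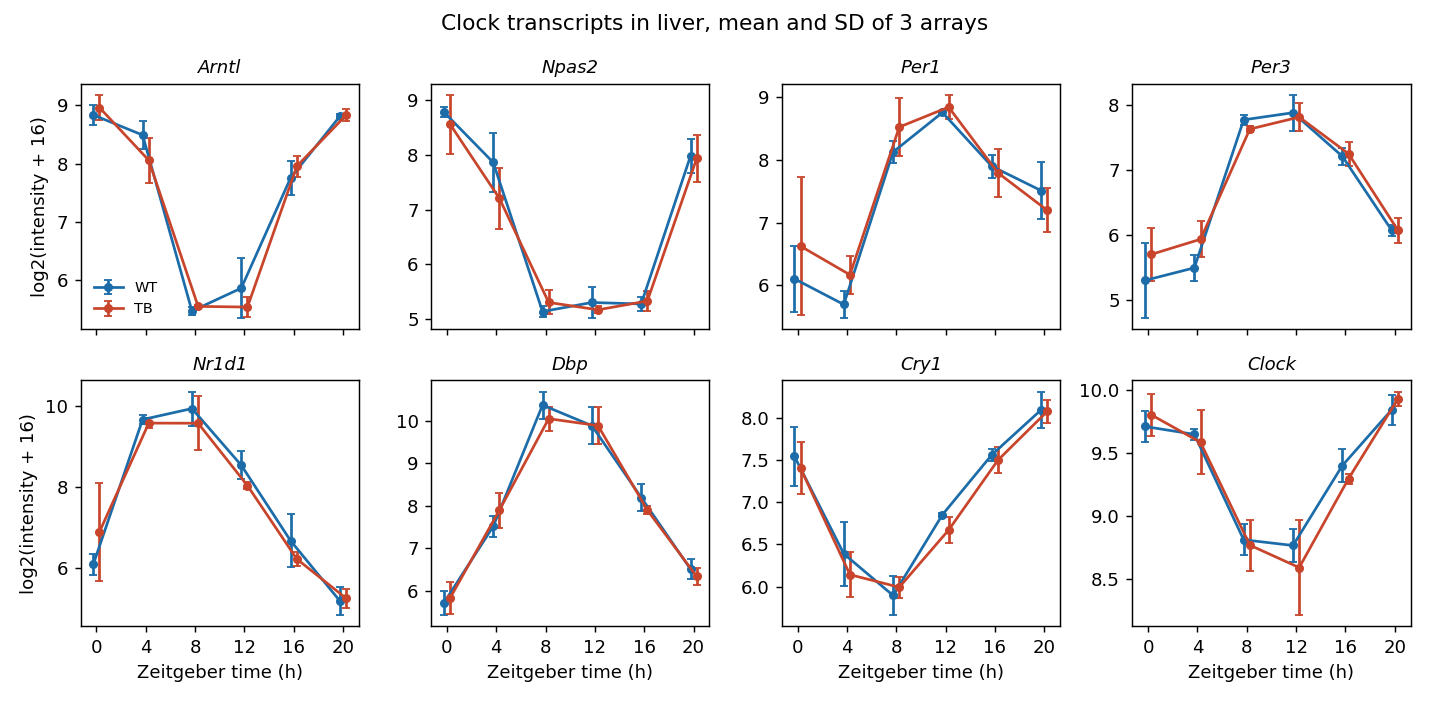
Log2 level (vertical axis) of Arntl, Npas2, Per1, Per3, Nr1d1, Dbp, Cry1 and Clock at the 6 times (horizontal axis, ZT in h) in WT (blue) and TB (red), as mean and SD of 3 arrays. Arntl peaked at ZT 22.4 in WT and 22.1 in TB and Nr1d1 at ZT 7.76 and 6.92.

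Over all genes 1430 were rhythmic in WT and 1099 in TB, and 594 in both, where 70.9 would be shared by independent lists. Dbp, a PAR bZIP transcription factor under direct clock control, had the smallest p for a rhythm in WT over the 36 arrays, with amplitudes of 2.34 and 2.25 (SE 0.121) and peaks at ZT 10.5 and 10.1 (adjusted p = 3.8e-15 in WT and 6.8e-15 in TB). The choline kinase gene Chka had amplitudes of 1.37 and 1.54 with peaks at ZT 22.2 and 21.9 and the smallest p in TB (adjusted p = 4.7e-16), the mitotic kinase gene Wee1 amplitudes of 1.45 and 1.06 and the tubulin gene Tubb2a of 1.40 and 1.78. Grk5 had 1.09 and 0.72. In the 594 shared genes the median amplitude was 0.379 in WT and 0.365 in TB, the amplitude was lower in TB in 340 (57.2%), the median difference in peak time was −0.57 h, and 530 (89.2%) peaked within 2 h of each other.

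The counts of 836 genes rhythmic only past the WT threshold and 505 only past the TB threshold do not show that these genes differ. Of the 836, 395 had an unadjusted p under 0.05 in TB, and of the 505, 207 had one in WT. The test of the difference in rhythm called 0 of 22180 genes in limma (1064 at an unadjusted p under 0.05, lowest adjusted p = 0.190; no other tool was run). Adjusted only over the 1935 genes rhythmic in either genotype it called 2, Cryga and Wif1 (adjusted p = 0.0166 each), and over all genes it called 1 without WT ZT 8 replicate 2. With the array set as a block 2002 genes were rhythmic in WT, 1660 in TB, 845 in both, and 0 differed (1593 unadjusted). The larger set alone gave 1459 and 944, and the smaller 16 and 19. The Kendall rank test gave 971 and 578, with 265 in both.

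Peak times of rhythmic genes were counted in bins of 4 h. Of the genes rhythmic in TB 515 (46.9%) peaked between ZT 20 and 24, against 179 (12.5%) of those rhythmic in WT, which most often peaked between ZT 8 and 12 (426 genes). With the array set as a block the shares between ZT 20 and 24 were 45.8% and 12.3%, in the larger set alone 53.0% and 10.7%, and in the smaller, where only 19 and 16 genes were rhythmic, 42.1% and 43.8%. By the rank test they were 46.4% and 12.8%. With the array set as a block, 20 of 100 splits of genotype within ZT and array set, the real one included, gave as large a difference between the peak shares.

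**Figure D4:**
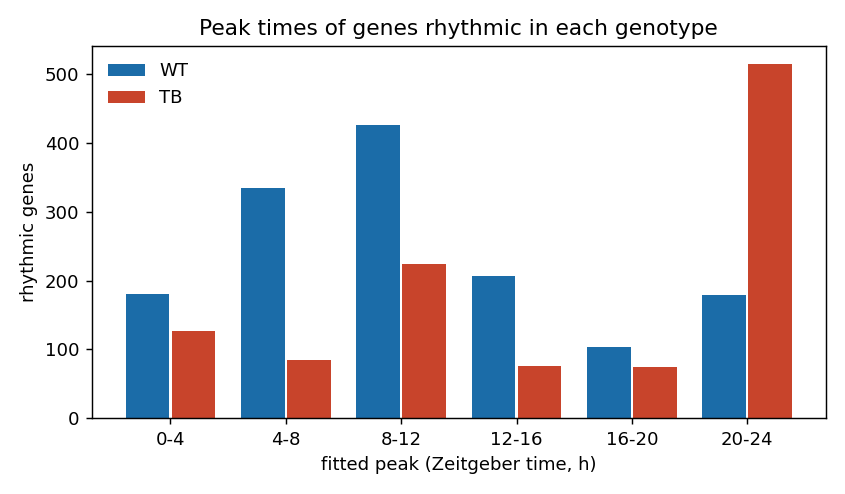
Number of rhythmic genes (vertical axis) by peak time in bins of 4 h (horizontal axis, ZT in h) in WT (blue) and TB (red). TB has 515 genes and WT 179 in the bin from ZT 20 to 24, and WT has 426 and TB 224 in the bin from ZT 8 to 12.

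Several lists held more rhythmic genes than independent draws of genes would give. Genes of a list can move together, which Fisher's exact test ignores, so its p-values here are likely too small. Besides the core clock (adjusted p = 1.7e-13 in WT and 1.4e-11 in TB by Fisher's exact test) and clock-controlled output genes (11 of 11 in WT and 10 in TB), heat shock chaperones were rhythmic in 13 of 15 cases in WT and 12 in TB (adjusted p = 6.2e-13 and 2.4e-12), with 12 in both. Unfolded protein response genes were rhythmic in 12 and 15 of 26 cases (adjusted p = 2.1e-07 and 2.4e-12), bile acid genes in 8 and 8 of 22 (0.00029 and 3.7e-05), glucocorticoid response genes in 7 and 8 of 17 (0.0003 and 4.8e-06) and urea cycle and amino acid genes in 11 and 6 of 35 (6.4e-05 and 0.0223). Fatty acid synthesis genes were rhythmic in 6 and 9 of 24 cases (0.00978 and 8.1e-06). Cholesterol synthesis genes were rhythmic in 1 of 19 cases in WT and 7 in TB (0.914 and 0.000113), and interferon response genes in 7 of 21 in WT and 0 in TB (0.00125 and 1). The rhythm of the list scores did not differ between genotypes for either (adjusted p = 0.294 and 0.248) or for any list, with 0.0612 the lowest, for oxidative phosphorylation and glycolysis.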

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

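The tests of this part were chosen only after the results were seen, except the random lists matched on intensity.

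Cryga, a lens crystallin gene, was rhythmic in TB (adjusted p = 0.00172, amplitude 0.35, peak at ZT 10.8) and not called in WT (adjusted p = 0.363, fitted amplitude 0.15 and peak at ZT 22.6), and its test of the difference in rhythm gave adjusted p = 0.0166 over the genes rhythmic in either genotype and 0.190 over all genes. Wif1, a secreted Wnt inhibitor gene, had amplitudes of 0.26 and 0.24 with peaks at ZT 0.25 and 11.2, adjusted p = 0.0166 and 0.190 in the same tests, and the smallest p of the interaction with time (adjusted p = 0.0928). Among all 41345 probe sets, named or not, 26 differed between TB and WT, and 7 of these have no symbol, a signal outside the gene tests. A component of the probe sets without a symbol, none of which enters a gene test, took 33.6% of their variance within groups and parted the arrays into sets of 12 and 24.

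The first pattern is the genes that differed between genotypes in the larger array set, 1151 of them, and with them the mitochondrial ribosomal protein genes. Of the 1151, 42.7% had the same sign in the smaller set (179 of 331 higher and 312 of 820 lower genes). A processing difference that goes with genotype inside the larger set would give a share as low. All genes gave 43.5%, however, so this share is not particular to the called genes and cannot decide the question. The 70 mitochondrial ribosomal protein genes had a mean of −0.14 in the larger set and 0.0014 in the smaller, as such a processing difference would also give. Muscle RNA in 1 array of the smaller set as the cause of the missing relation was argued against, since r between the sets stayed at −0.042 without that array. Of the 36 largest differences (0.5 log2 or more) 26 kept their sign, so part of the pattern may be a genotype effect, which stays open. The biological difference between TB and WT in the larger set alone remains a hypothesis.

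The second pattern is the higher acute phase and IL-6 lists and the lower oxidative phosphorylation and fatty acid synthesis lists. A processing difference inside the larger set as the whole cause was argued against for the first pair. Their means in the smaller set were 1.28 and 1.65 times those in the larger, at the smallest p that set allows. Without the muscle-bearing array they were 1.05 and 1.44 times, with an exact permutation p of 0.0625 each from fewer arrangements. Other lists reached the smallest p of the smaller set too. These were glucocorticoid response (0.23 in the larger set and 0.22 in the smaller), red cells and platelets (0.029 and 0.081) and, with opposite signs, unfolded protein (−0.16 and 0.14). Separate differences in each set therefore stay open. A processing difference cannot be told apart for oxidative phosphorylation (ratio 0.757, and 0.382 without that array, where −0.059 ± 0.048 is too uncertain to decide) and fatty acid synthesis (1.03), whose exact permutation p in the 12 arrays were 0.188 and 0.0625. More blood or immune cells in TB pieces cannot be told apart. Lymphocyte genes went both ways (mean 0.011, 10 of 19 positive), while Kupffer cell (mean 0.13) and neutrophil (0.059) lists and Elane (0.26) were higher. Red cell and platelet genes, not called by camera, were positive in 6 of 7 cases (mean 0.046), with means of 0.029 in the larger set and 0.081 in the smaller. A shift of all genes of like intensity as the whole cause was argued against by 10000 matched random lists. Of these 0% had a mean as low as that of oxidative phosphorylation (lowest −0.13), but their median was −0.035, so such a shift may hold a part. Their genes were drawn independently, while those of the list had an estimated correlation of 0.14, so the spread of the random lists may be too narrow. Loss of short abundant transcripts was argued against by a median of 0.0026 of the cytosolic ribosomal protein genes (SD 0.079). Mislabelled TB samples at WT ZT 0 replicate 2 and WT ZT 12 replicate 1 cannot be told apart from WT samples in an acute phase. The first had an oxidative phosphorylation score of −0.088 (the TB mean over all times was −0.071) and the other of 0.0087. For the first this score could not decide, since it did not part the genotypes at ZT 0. The other WT arrays there scored −0.041 and −0.0064, and the TB arrays −0.060, −0.060 and 0.074. A response of the liver to the tumour is among the open explanations, as a hypothesis, and a difference in handling between genotypes that affects both sets was not tested.

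The third pattern is the peak times of rhythmic genes, with 46.9% of TB and 12.5% of WT rhythmic genes peaking between ZT 20 and 24. A time course of processing inside the larger set was argued against as the source of the TB peak times alone. Of the genes rhythmic in TB there, 89.1% peaked within 4 h of the same time in the TB arrays of the smaller set. That share was reached in 1 of 100 orders of those 6 arrays, the real one (median of the others 26.5%, highest 86.0%). For the difference between genotypes this test cannot decide, since 87.2% also peaked within 4 h in the WT arrays of the smaller set. In that set 42.1% of 19 rhythmic TB genes and 43.8% of 16 rhythmic WT genes peaked between ZT 20 and 24. Rhythms that WT livers lack cannot be told apart from shared ones, since of the 500 genes that peaked between ZT 20 and 24 in TB of the larger set 87.2% peaked within 4 h of that time in WT arrays of the smaller set (2 of 100 orders as high) and 79.0% in those of the larger (5 orders), and of the 364 of them not called in WT 83.0% and 72.8% (3 and 5 orders, highest others 87.1% and 77.5%), with median amplitudes of 0.12 log2 in WT and 0.28 in TB of the larger set, where they were chosen by their TB rhythm, and of 0.19 and 0.22 in the smaller. The difference may lie in part in which genes pass the threshold, as a hypothesis, but chance is not excluded for it, since 20 of 100 splits within ZT and array set gave peak shares as far apart (33.6 percentage points with the set as a block, highest other 43.4). Whether food intake or activity differed between the genotypes was not tested.

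Other splits of the arrays, 100 each with the real one, were drawn for each count. For the 39 genes over all times 2 splits, the real one included, were as large. This makes chance less likely but does not exclude it, since these splits ignored the array sets. The highest other split called 292 genes, several times more, and put 11 of the 12 arrays of the smaller set on 1 side, which points to the structure of the samples. With the set as a block 151 genes were called (highest other 2, 1 split as large), and in the larger set 1151 (highest other 1, 1 split as large). The sets were found from the real groups and were not found anew in each split, so chance is not excluded by these counts. For the 15 lists called by camera it cannot be excluded (highest other 20; 10 splits). For the interaction and for differential rhythm all 100 splits gave as many genes, since the real count was 0 in each (highest other 1). Chance is an unlikely source of the counts of rhythmic genes in WT (1430, highest other order of times 107) and TB (1099, highest other 102). These orders ignored the array sets, and 1 in 100 is the smallest share they allow. For the difference in peak shares, 34.3 percentage points, 4 splits that ignored the array sets were as large (highest other 37.7), and 4 for a median peak shift of 0.631 h in genes rhythmic over both genotypes (highest other 0.862 h). With splits within the sets and the set as a block these were 20 for the shares and 5 for the shift (highest other 0.857 h), so chance cannot be excluded for either. For the 1341 genes rhythmic in 1 genotype by the threshold (highest other 1920; 16 splits) and for a median amplitude difference of 0.0226 log2 (highest other 0.0482; 28 splits) it cannot be excluded. At single times the 10 splits of 6 arrays are too few for a share under 0.05. The real counts there were 0, 0, 1, 0, 0 and 0 and the highest others 2, 1, 2, 1, 0 and 0 from ZT 0 to ZT 20.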

How the results depend on the processing

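The tests without ZT 0, by array set and by permutation of list scores were chosen only after the results were seen, and the others were fixed before. The 39 genes of TB vs WT mean over 6 times became 47 after quantile normalization or median centring, 54 without the third of genes lowest in mean, 29 with a variance trend, 44 with additive time, 26 over all probe sets and 38 with the replicate block. They became 15 with a pseudocount of 1, 626 with array weights, 14 with the Xist covariate, 77 without ZT 0, 151 with the array set as a block, 183 with that block and no muscle-bearing array, 1151 in the larger array set alone and 0 in the smaller array set alone (1971 unadjusted). Except where fewer arrays were fitted, the cause was not tested. Pooled over all times, replicate numbers did not pair the arrays: same-numbered arrays correlated at −0.004 in their deviations and others at 0.005, 74 of 198 pairs were over 0.1 and 11 of 36 arrays were closest to their own number. Within each ZT, however, the array of the smaller set had the same replicate number in WT and TB, and pairs inside a ZT were not tested alone. With the replicate block 1394 genes were rhythmic in WT and 1053 rhythmic in TB, with 15 lists called and 0 genes at ZT 8. Depth has no direct measure on arrays, and 23.0% of values under 16 intensity units limit what dim genes can show.

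At ZT 0, 2 genes were called in the larger set and with the block without the muscle-bearing array. At ZT 4, 1 was called with a pseudocount of 1 and with either block, and 2 with array weights. At ZT 8, 0 were called with a pseudocount of 1, median centring, the replicate block and the Xist covariate, 2 with quantile normalization, without the third lowest in mean, with a variance trend, with only the arrays of that ZT, without ZT 0 and with the array set as a block, 4 with that block and no muscle-bearing array, 28 in the larger set and 62 with array weights. At ZT 16, 1 was called with array weights. Genes rhythmic in WT numbered 2251 with array weights, 597 with a 6-level time factor and 16 in the smaller set. Those rhythmic in TB numbered 1989, 482 and 19, and 578 by the Kendall rank test, 1660 with the array set as a block and 1825 with the block without the muscle-bearing array. Differential rhythm adjusted over genes rhythmic in either gave 2. Lists called numbered 1 with an estimated correlation, 5 by fry, 3 by permutation of list scores, 9 in the smaller set and 11 there without the muscle-bearing array.

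Signs turned for Eif2s3y, not called, with median centring (−0.0045), array weights (−0.032), without ZT 0 (−0.057), with the block without the muscle-bearing array (−0.0082) and in the larger set (−0.10), and for Uty with median centring (−0.022), array weights (−0.044), without ZT 0 (−0.032) and in the larger set (−0.083), where Irs2 also turned (−0.0099). In the smaller set Bst2 (0.0017), Rtp4 (0.13), Usp18 (0.23), Got1 (−0.014), Ghr (0.079), Ugt2b5 (0.033), Hyou1 (0.12), Manf (0.10), Hsp90b1 (0.065), Dkc1 (0.040), Wdr12 (0.12) and Kdm5d (0.037) turned, as did the lists for interferon (0.094), phase II (0.055), unfolded protein (0.14), ribosome biogenesis (0.078) and male-biased genes (0.11), and without the muscle-bearing array these 5 again (0.055, 0.078, 0.16, 0.051 and 0.21). The list on insulin and growth factor signalling, not called before, was called higher in the smaller set, against a downward test over all arrays, with adjusted p = 0.0232, and 0.00966 without the muscle-bearing array. Of the other single results, calls were lost most often in the smaller set (56), with the Xist covariate (21) and with a pseudocount of 1 (17), and gained most often with array weights (27) and in the larger set (23).

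With single arrays left out, genes over all times ranged from 11 to 109 and left the 1.5-fold range in 27 of 36 cases, with 104 without WT ZT 12 replicate 1, 92 without TB ZT 0 replicate 3 and 71 without WT ZT 8 replicate 2. Counts ranged from 0 to 5 at ZT 0, 0 to 1 at ZT 4, 0 to 7 at ZT 8 and 0 to 20 at ZT 12, and were 0 at ZT 16 and ZT 20. The interaction ranged from 0 to 3, rhythmic genes from 1115 to 1543 in WT and 759 to 1502 in TB, differential rhythm from 0 to 1, lists from 11 to 16, and the share of peaks between ZT 20 and 24 from 42.3% to 52.2% in TB and 10.4% to 14.8% in WT. Uty ranged from −0.013 to 0.031 and Eif2s3y from −0.0081 to 0.054.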

Other observations

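The tests of this part, with the array set as a block, with the added ribosomal lists and on the rhythm of list scores, were chosen only after the results were seen. With the array set as a block, TB livers differed in 151 genes, and the rule for named genes applied to them gave further genes with 1 sign at all 6 times. Prtn3, the proteinase 3 of neutrophil granules, rose by 1.52 ± 0.342 log2 (limma adjusted p = 0.0305, n = 18 per genotype), beside the rise of Elane in the test without the block. The integrin Itgb3 of platelets rose by 0.45 ± 0.097 (adjusted p = 0.0256), the langerin gene Cd207 by 0.38 ± 0.080 (0.0228) and Sting1, an adaptor of DNA sensing, by 0.38 ± 0.087 (0.0324). Timp3, an inhibitor of matrix metalloproteinases, decreased by 0.38 ± 0.089 (0.0398), and Terc, the RNA of telomerase, decreased by 0.37 ± 0.083 (0.0288), beside the decrease of Tert. Other lower genes were Mrps35 of the mitochondrial ribosome at −0.29 ± 0.044 (0.00114), the ferredoxin Fdx1 at −0.29 ± 0.065 (0.0327), the complex III assembly factor Uqcc1 at −0.27 ± 0.055 (0.0228) and the complex I subunit Ndufb10 at −0.24 ± 0.051 (0.0228). In the smaller set alone the values were 1.76 for Prtn3, −0.17 for Mrps35, −0.022 for Fdx1 and −0.20 for Ndufb10.

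Mitochondrial ribosomal protein genes were lower in TB, with 64 of 70 negative, a mean of −0.095 and a median of −0.094 log2 (camera p = 1.6e-17, and p = 0.00414 with an estimated correlation). With the array set as a block the adjusted p over the added lists was 0.0300 with an estimated correlation, yet the mean was −0.14 in the larger set and 0.0014 in the smaller. Cytosolic ribosomal protein genes had a mean of 0.0063 and a median of 0.0026 over 67 genes, with 38 positive. Among rhythmic genes, cytochrome P450 genes numbered 5 of 29 in WT and 8 in TB (adjusted p = 0.0890 and 0.000279 by Fisher's exact test), autophagy genes 6 and 5 of 17, with 5 in both, and endothelial markers 6 and 1 of 19. The rhythm of their list scores did not pass the test of a difference between genotypes (adjusted p = 0.136, 0.294 and 0.321).

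TB minus WT differences over genes were related between times in the larger set, with r from 0.187 to 0.497 among ZT 0 to ZT 16, but from −0.268 to −0.050 with ZT 20, and from −0.045 to 0.136 in the smaller set (across genes, which are not independent replicates). The genotype effect differed between the sets in 154 genes by limma.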
